A study of Arabidopsis thaliana with 4 samples.

How the data were processed

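RNA was sequenced from hypocotyls, the embryonic stems, of Arabidopsis thaliana seedlings grown in darkness for 4 days. Seedlings of the wild type Col-0 and of arf7, a T-DNA insertion mutant of the auxin response factor ARF7, were grown with 500 nM of the synthetic auxin naphthalene acetic acid (NAA) or without it (mock). That gave 4 libraries, 1 per combination of genotype and treatment. Per the labels, total RNA was purified on silica columns, copied with random primers and sequenced on an Illumina HiSeq instrument, and the labels allow for another sequencer where needed.

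For each library the authors deposited a count of uniquely assigned reads per transcript model, per the file headers, with models that had no read left out. The same tables hold the model length, the percent of the model covered by reads and an RPKM value, all made by the authors, per the file headers. The deposited RPKM was recomputed from the counts, the lengths and the library total and matched within rounding. The genome build was TAIR10, per the submitters' processing notes, and the aligner and the counting tool were not given in the sources used here. The authors also deposited 4 tables of their own comparisons, which list a log2 ratio of RPKM, a p-value and an FDR for each model past their filter. On inspection those tables hold only models with an absolute log2 ratio of at least 1.00 and an FDR of at most 0.001, and an RPKM of 0 was replaced by 0.01. The test behind the authors' p-value and FDR was not given in the sources used here. A further 16 columns of per-sample values in those tables were not used.

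The covered part of a model differed with the number of models listed for its locus. Loci with 1 listed model (20314 of them) had a median of 70.7% of the model covered, while the 7289 models of the 3381 loci with 2 or more listed models had a median of 5.37%. Reads in sequence shared by the models of a locus therefore appear to be missing from the counts, and such loci were measured on a small part of their length. Since models with no read are not listed, a locus with 1 listed model may have others. Keeping only loci with 1 listed model may thus not remove all such loci. Reads were summed per locus, a choice made after the files were inspected, and the transcript models as deposited and loci with 1 listed model were run as alternatives. The same counting leaves near-identical paralogs uncertain, among them SAUR19 to SAUR24, SAUR61 to SAUR68, the LHCB1 and LHCB2 copies and the RBCS genes. The labels do not say that counting used strand, so overlapping and antisense genes are uncertain too.

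The design had been written for counts per gene, and its rules were applied to the locus sums. Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3. The TMM factors were 0.991 for Col-0 mock, 0.947 for Col-0 NAA, 1.04 for arf7 mock and 1.03 for arf7 NAA. Loci with a mean of at least 1 CPM (counts scaled to a common library size) over the 4 libraries were compared, which were 17317 of the 23695 loci with any read. A locus could pass through 1 library where it was high, which favours list members higher in that library. Because each group is 1 library, no difference has a replicate check and no p-value across genes is given for the pairwise comparisons. A size rule was used in place of a test, and it asked for a fold of at least 2 with a 95% counting interval that excludes 1. The interval is the exact conditional binomial (Clopper-Pearson) interval of the ratio of 2 counts. It compares 2 libraries and not 2 conditions, and intervals and floors cover counting error only. A count of 0 was taken as at most 3 counts, so a fold against 0 is a lower bound against that floor in that library, and it leaves out the counting error of the other library. Log2 folds were computed after adding 0.5 to each count.

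A response was called weaker in arf7 where a locus met the size rule with NAA in Col-0 and the arf7 log2 response was shifted against the Col-0 direction by at least 1 with a 95% Wald counting interval that excludes 0. A response was called stronger where a locus met the rule in arf7 and its log2 response there lay at least 1 further in its own direction than that of Col-0, with an interval that excludes 0. A locus with opposite responses in the genotypes can meet both definitions. The slope of the arf7 response on the Col-0 response was taken through the origin over the loci that met the rule in Col-0, and also the other way round. An additive model of genotype and treatment was fitted to all 4 libraries with the quasi-likelihood test of edgeR, which leaves 1 residual degree of freedom and counts any interaction as error. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives.

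Lists of genes were fixed for 26 functions and tissues, namely Aux/IAA repressors, GH3 and DAO enzymes, SAUR genes, ARF factors, LBD and other root initiation regulators, auxin transport, auxin receptors, auxin biosynthesis, ethylene biosynthesis, ethylene response, gibberellin, brassinosteroid, cytokinin, expansins, XTH enzymes, cell division, flavonoid synthesis, photosynthesis, root and root hair markers, shoot apex markers, seed storage, PIF with HD-ZIP II and PRE regulators, defence and jasmonate, abscisic acid, low oxygen and heat shock. The photosynthesis, root, shoot apex and seed lists stand for other tissue that dissected hypocotyls could hold. The median log2 fold of each list was set beside 10000 random lists of the same size, matched on mean expression in 20 bins, and this percentile is a description of these libraries. The lists, the sample groups, the comparisons, the size rule and the rule for named genes were fixed before the data were examined. The lists were drawn up from memory, and of their 409 genes 405 had a symbol that matched the locus in the files or the annotation and 398 had a read. The DAO genes were named from their locus. The single value of 1 gene in the list of root genes outside hairs is not reported here.

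The rule for named genes put ARF7 before the others. In each comparison it then took from every list up to 4 members that met the size rule and had the largest absolute log2 fold, and the 5 largest increases and 5 largest decreases among loci with a symbol and a mean of at least 10 CPM. For the difference in response it took the 5 largest weaker and the 5 largest stronger differences at the same minimum. Symbols came from the gene lists, the files and the gene table of the reference annotation (TAIR10.1, used for names only). That gene table held 23505 of the 23695 loci, and 9761 loci had a symbol from any of these sources. Positions are those in the files' descriptions on TAIR10.

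The libraries held 7406802 counts in Col-0 mock, 7174313 in Col-0 NAA, 6996903 in arf7 mock and 7201846 in arf7 NAA. At this depth, 2 loci at 100 counts each have a fold of 1 with a counting interval of 0.750 to 1.33, and at 1000 counts each the interval is 0.915 to 1.09. A count of 0 allows up to 0.405, 0.418, 0.429 and 0.417 CPM in the 4 libraries in the same order. The steps were tested on simulated data. For the comparison of NAA with mock in Col-0, run on 17317 loci, the size rule recovered 88% of 100 loci changed 2.83-fold and 100% of 100 changed 4-fold, and 123 unchanged loci met it. These counts were simulated with Poisson counting error only, without any spread between plants. The 123 therefore give no false-call rate for the real single libraries. The intervals held the simulated fold in 93%, 98% and 95.4% of the 2.83-fold, 4-fold and unchanged loci, and a slope of 0.4 was recovered as 0.395. For the additive NAA effect, also on 17317 loci, edgeR recovered 14% of 100 loci changed 2-fold and 87% of 100 changed 4-fold with 4 false calls at a simulated biological coefficient of variation of 0.224. At the 0.360 of the real fit, a simulation added after the results were seen, it recovered 1% and 17% with 1 false call.

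The alternatives tried were scaling by total counts and by DESeq2 size factors, no expression filter and a mean of at least 5 CPM, a fold of at least 3, the deposited RPKM on a log2 scale with 1 or 0.1 added, the calls in the authors' deposited tables, list means in place of medians and lists without near-identical SAUR members. Those chosen after seeing the data were the transcript models as deposited, loci with 1 listed model, and scaling and filtering without the Col-0 NAA library. The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.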

Results

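Etiolated hypocotyls of Col-0 and of the arf7 T-DNA mutant were profiled with and without the synthetic auxin NAA, to ask which part of the auxin response of this organ differs without ARF7, a transcription factor that activates auxin-responsive genes. There were 4 libraries, 1 for each of Col-0 mock, Col-0 NAA, arf7 mock and arf7 NAA, at similar depth. No group had a replicate, so every comparison is between single libraries, and ranges in parentheses after a fold are 95% counting intervals that leave out any spread between plants. A fold of at least a value, against 0 counts, sets the 0 at 3 counts and leaves out the counting error of the other library.

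ARF7 (AT5G20730, chromosome 5, 7016445 to 7022042, reverse strand, TAIR10) was barely measured. Its listed model had reads over 1.57% of its length and held 8 counts in Col-0 mock, 8 in Col-0 NAA, 3 in arf7 mock and 1 in arf7 NAA. The arf7 libraries together held 4 reads against 16 in Col-0, a fold of 0.241 (0.0586 to 0.747), lower in the direction of the labels. The mean of 0.691 CPM was below the minimum for the comparisons, and where the counted sequence lies relative to the insertion is not known from the sources used here.

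With NAA, 19 of 25 SAUR growth genes, 10 of 13 expansins and 5 of 8 auxin-inactivating enzymes were higher in the Col-0 library, and 6 of 7 heat shock and 8 of 10 defence and jasmonate genes were lower. GH3.2 (AT4G37390, chromosome 4, 17579657 to 17582022), which couples auxin to amino acids, had 51.3-fold more reads with NAA than in mock (36.9 to 73.5). XTH15 (AT4G14130, chromosome 4, 8137051 to 8138281), a xyloglucan-modifying enzyme, was 158-fold higher (130 to 194), with 15219 counts against 104. HSP90.1, a heat-inducible chaperone, was 24.4-fold lower (20.2 to 29.6) and CYP81F2, an enzyme of indole glucosinolate modification, 27.6-fold lower (21.2 to 36.5). In all, 2626 loci met the size rule as higher and 2265 as lower, 28.2% of the 17317 compared.

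Among auxin genes, 19 of 25 measured SAUR genes were higher and 0 lower (median log2 2.36, percentile 100 of random lists, or 1.297 without the near-identical copies). SAUR16 was 41.1-fold higher (17.3 to 128) and SAUR50 11.4-fold (7.97 to 16.7), while SAUR20 at 12.6-fold (6.12 to 30.0) and SAUR23 at 10.8-fold (5.23 to 25.9) belong to a group of near-identical copies that share reads. Of 8 GH3 and DAO genes, 5 were higher and 1 lower (median 1.59, percentile 100). GH3.1 was 7.63-fold higher (5.71 to 10.4) and GH3.17 4.39-fold (3.23 to 6.06), whereas DAO2, of the auxin oxidase family, was 6.64-fold lower (5.36 to 8.31). The Aux/IAA repressors were mixed, with 5 of 21 higher and 2 lower (median 0.42, percentile 98.2). IAA20 had 0 counts in mock and 165 with NAA, at least 59.5-fold higher, IAA6 was 11.3-fold higher (6.22 to 22.4) and IAA17 3.4-fold (3.14 to 3.68), while IAA27 was 3.57-fold lower (3.02 to 4.24).

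LBD29 and LBD18, regulators of lateral root initiation, were 20.07-fold (12.2 to 35.6) and 7.73-fold higher (4.82 to 13.0), the 2 of the 4 measured genes of their list that met the rule (median 1.94, percentile 99.0). The ARF list had 4 of 12 members higher and 1 lower (median 0.24, percentile 83.5), led by the repressor-type factors ARF10 at 3.43-fold (2.90 to 4.07) and ARF16 at 3.28-fold (2.70 to 4.01). Of 6 auxin receptor genes 5 were higher (median 1.21, percentile 99.8), among them the kinase TMK1 at 4.27-fold (3.93 to 4.65) and the F-box gene AFB1 at 3.76-fold (3.22 to 4.41). Auxin transport had 5 of 17 members higher and 2 lower (median 0.78, percentile 99.9). PIN2, an efflux carrier of roots, was 21.0-fold higher (12.3 to 38.9), the kinase gene WAG1 13.9-fold higher (10.2 to 19.4) and PIN6 14.3-fold lower (6.34 to 40.1). Auxin biosynthesis went both ways, with 3 of 7 higher and 2 lower (median 0.11, percentile 58.5), from YUC8 at 30.0-fold higher (11.4 to 112) and TAA1 at 7.06-fold (4.85 to 10.6) to YUC6 at 4.29-fold lower (2.21 to 9.12).

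Expansins were among the lists with the largest medians. Of 13 expansins, which loosen cell walls, 10 were higher and 3 lower (median 2.69, percentile 100). EXPA11 was 27.6-fold higher (21.7 to 35.6) and EXPB1 39.6-fold (16.7 to 123), and EXPA17 had 100 counts against 1, a ratio of 108 (19 to 4313). Reads of EXPB3, 19.9-fold lower (12.8 to 32.4), covered only 8.08% of its model. Of 12 XTH genes 7 were higher and 2 lower (median 1.43, percentile 100), with XTH17 at 46.8-fold (38.8 to 57.0), XTH33 at 20.11-fold (10.7 to 42.6) and XTH19 at 16.4-fold (14.3 to 19). The PIF, HD-ZIP II and PRE list had 9 of 12 members higher (median 1.53, percentile 100), including PRE6 at 7.10-fold (5.83 to 8.73) and PRE1 at 5.61-fold (3.26 to 10.3), which encode growth-promoting atypical bHLH proteins.

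The lists of other hormones went both ways. In ethylene biosynthesis 3 of 8 were higher and 1 lower (median 0.65, percentile 96.4), with ACS5 at 186 counts against 2, a ratio of 101 (27.4 to 836), ACO4 at 4.21-fold (3.77 to 4.71) and ACS6 2.72-fold lower (2.52 to 2.95). In ethylene response 4 of 8 were higher (median 0.82, percentile 98.9), among them the apical hook regulator HLS1 at 14.3-fold (8.49 to 26.1) and EBF2 at 2.66-fold (2.5 to 2.83). The gibberellin list had 3 of 11 higher and 2 lower (median 0.04, percentile 53.6), with the biosynthetic GA3OX1 4.14-fold higher (3.04 to 5.73) and the inactivating GA2OX6 3.69-fold lower (3.26 to 4.20). In the brassinosteroid list 1 of 8 met the rule (median 0.58, percentile 97.6), the inactivating enzyme gene BAS1 at 2.49-fold (2.09 to 2.97). Among cytokinin genes 3 of 11 were lower and 1 higher (median -0.51, percentile 4.68). The lower ones were the type-A response regulators ARR7 at 13.7-fold (9.57 to 20.3), ARR5 at 4.71-fold (3.89 to 5.75) and ARR6 at 3.65-fold (2.78 to 4.83). In the abscisic acid list 3 of 4 were higher (median 1.59, percentile 98.3), for example KIN1 at 3.56-fold (2.36 to 5.50).

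The heat shock list and the defence and jasmonate list stood at the lower end. Of 7 heat shock genes 6 were lower (median -2.41, percentile 0.02), with HSP70 (AT3G12580) at 633 counts against 10083, 14.7-fold lower (13.6 to 16.0), and HSP101 4.72-fold lower (4.16 to 5.38). In the defence and jasmonate list 8 of 10 were lower and 0 higher (median -2.32, percentile 0.00), including WRKY40 at 5.36-fold (4.92 to 5.85) and the camalexin gene PAD3 at 5.42-fold (2.41 to 14.3). The low-oxygen list went the other way, with 6 of 6 higher (median 2.43, percentile 100), among them PCO1 at 16.6-fold (10.3 to 28.4) and PDC1 at 7.78-fold (4.52 to 14.4). Flavonoid genes were mixed, 3 of 6 higher and 1 lower (median 0.98, percentile 95.4, or -0.51 with no expression filter), the lower being chalcone synthase, CHS, at 2.37-fold (2.09 to 2.69). Cell division genes did not differ as a group, with 1 of 20 higher and 1 lower (median -0.05, percentile 45.9). CYCD3;1, a cyclin of the transition into DNA replication, was 3.0-fold lower (2.60 to 3.46).

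Lists for other tissues differed too. Of 13 root and root hair markers 12 were higher (median 3.87, percentile 100, or 3.71 with zero counts at their bound), among them LRX1, a cell wall protein of root hairs, at 194 counts against 3, a ratio of 69.9 (23.6 to 342), and XTH14 at 200 against 2, a ratio of 108 (29.5 to 899). Only 4 of the 13 reached 1 CPM in Col-0 mock. The others passed the expression filter through other libraries, so the filter itself favours a high share. In the seed storage list 3 of 4 were higher (median 3.39, percentile 99.4) with at most 38 counts each, and of the shoot apex list 2 genes were measured and STM was 2.20-fold higher (1.43 to 3.44; list median 0.67, percentile 79.2). The photosynthesis list split, 5 of 18 higher and 4 lower, and its median of -0.56 (percentile 1.1) and its mean of 1.02 differ in sign. ELIP1 and ELIP2, early light-induced proteins, were 140-fold (71.0 to 326) and 245-fold higher (95.5 to 903), while LHCB1.1, a light-harvesting antenna protein, was 7.63-fold lower (6.80 to 8.58). Reads of LHCB1.1 may be shared with its near-identical copies, and the 5 LHCB1 copies summed to 85503 counts in mock and 69596 with NAA, a much smaller difference. PORA, a protochlorophyllide reductase of dark-grown seedlings, had 373 counts with NAA and 0 in mock, at least 134-fold higher, from reads over 6.52% of its model.

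Among loci with a symbol and a mean of at least 10 CPM, the largest increases beyond these were in UMAMIT36 (0 to 529 counts, at least 191-fold), a member of an amino acid transporter family, the growth-regulating factor gene GRF7 (AT5G53660, 0 to 482 counts, at least 174-fold), the cellulase-family gene GH9B15 (0 to 350 counts, at least 126-fold) and CASP5, of the Casparian strip membrane protein family, at 575-fold (224 to 2111). The largest decreases were in EP1 (116 to 0 counts, at least 35.8-fold), BGLU7 (205 to 1 count, a ratio of 190 with an interval of 33.7 to 7525), the resistance gene RPP4 at 82.0-fold (37.4 to 224), IGMT1 at 66.7-fold (55.7 to 80.6) and WAK2 (243 to 3 counts, 74.9-fold with an interval of 25.3 to 366). The authors' deposited table for this comparison lists 2240 loci as higher and 1941 as lower, of which 2098 and 1789 met the size rule in the same direction. The Col-0 NAA library also stood apart from the other 3 as a whole, with a Spearman correlation across loci of 0.847 to 0.881 against 0.968 to 0.981 among the others. All values of this comparison rest on that library.

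**Figure D1:**
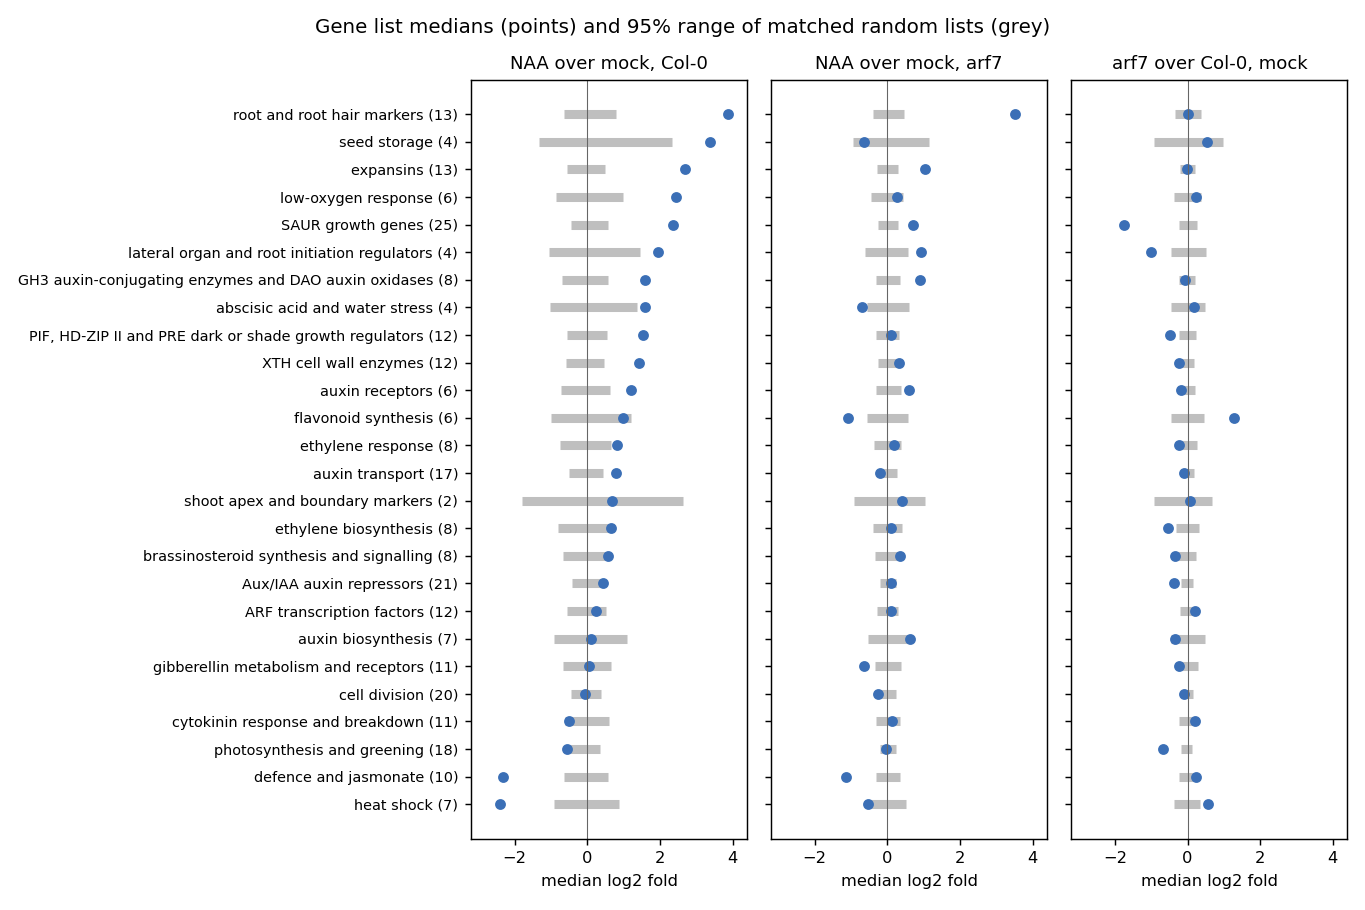
Median log2 fold (horizontal axis) of each of the 26 gene lists in 3 comparisons, with the number of measured genes in parentheses and a grey bar for the 95% range of 10000 matched random lists. The SAUR list lies at 2.36 with NAA in Col-0, at 0.71 with NAA in arf7 and at -1.75 in arf7 over Col-0 in mock.

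With NAA in arf7, fewer loci differed from mock. The size rule was met by 677 loci as higher and 749 as lower, 8.23% of those compared. GH3.2 was 4.37-fold higher (3.0 to 6.54), GH3.1 4.4-fold (1.45 to 17.9) and GH3.5 2.79-fold (2.40 to 3.24). Root and root hair markers were the list with the highest median, and defence and jasmonate genes the list with the lowest. The authors' deposited table lists 333 loci as higher and 484 as lower, and with a mean of at least 5 CPM the counts were 367 and 440.

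Of the auxin lists, GH3 and DAO genes had 3 of 8 higher (median 0.90, percentile 100). Of 25 SAUR genes 3 were higher and 1 lower, and the median of 0.71 (percentile 100) was -0.02 with zero counts at their bound. SAUR6 was 4.89-fold higher (2.67 to 9.66), SAUR72 3.87-fold higher (2.81 to 5.41) and SAUR41 2.28-fold lower (1.15 to 4.78). No Aux/IAA gene (0 of 21, median 0.11, percentile 81.1), ARF gene (0 of 12, median 0.11, percentile 76.9) or gene of the LBD list (0 of 4, median 0.94, percentile 99.7) met the rule. The receptor gene AFB1 was 2.98-fold higher (2.35 to 3.82), the only one of 6 (median 0.60, percentile 99.9). Auxin transport had 2 of 17 higher and 1 lower, with a median of -0.21 (percentile 4.80) and a mean of 0.01 that differ in sign. PIN2 was 5.15-fold higher (3.25 to 8.54), LAX1 2.29-fold higher (1.80 to 2.94) and the kinase gene WAG2 2.86-fold lower (2.01 to 4.13). Auxin biosynthesis had 1 of 7 higher and 2 lower (median 0.63, percentile 98.7), with YUC2 2.44-fold lower (1.52 to 4.02).

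Among wall genes, 6 of 13 expansins were higher and 1 lower (median 1.04, percentile 100), with EXPA11 at 8.47-fold (3.64 to 24.1), EXPA8 at 6.35-fold (3.85 to 11.1) and EXPA14 at 5.97-fold (2.93 to 13.7). Of 12 XTH genes 1 was higher and 1 lower (median 0.31, percentile 98.0), XTH24 at 2.07-fold (2.02 to 2.13) and XTH20 at 2.95-fold (2.49 to 3.5). Of 13 root and root hair markers 8 were higher and 1 lower (median 3.52, percentile 100, or 1.38 with zero counts at their bound). LRX1 had 88 counts against 2, a ratio of 43.0 (11.6 to 361), and PRP3, a wall protein of root hairs, was 30.7-fold higher (12.9 to 95.8). PRP1 and RHD6, a regulator of root hair formation, had 0 counts in mock and were at least 6.84-fold and at least 2.61-fold higher.

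Lower groups in arf7 with NAA were defence and jasmonate (7 of 10 lower, median -1.13, percentile 0.00), flavonoid synthesis (2 of 6 lower, median -1.09, percentile 0.03) and gibberellin (3 of 11 lower, median -0.65, percentile 0.03). PAD3 was 6.27-fold lower (2.94 to 15.3), JAZ10, a jasmonate-induced repressor, 5.31-fold (3.08 to 9.72) and the jasmonate synthesis gene AOS 2.89-fold (2.72 to 3.07). Chalcone isomerase, CHI, was 6.57-fold lower (4.61 to 9.61), CHS 2.55-fold (2.41 to 2.71), GA3OX1 2.59-fold (1.74 to 3.92) and the gibberellin receptor gene GID1B 2.16-fold (1.85 to 2.52). In the abscisic acid list 2 of 4 were lower, RD29A at 2.46-fold (2.28 to 2.66) and KIN1 at 2.42-fold (1.16 to 5.42), and the median of -0.70 (percentile 0.92) and the mean of 0.18 differ in sign. Of 7 heat shock genes 1 was lower (median -0.53, percentile 1.18), HSP101 at 2.84-fold (2.62 to 3.09). In the photosynthesis list 1 of 18 was lower (median -0.04, percentile 33.1), LHCB1.1 at 2.56-fold (1.5 to 4.54). The 5 near-identical LHCB1 copies together went the other way, with 27121 counts in mock and 32263 with NAA.

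In the remaining lists few members met the rule. Ethylene biosynthesis had ACS6 2.75-fold higher (2.57 to 2.94) and ACS8 2.43-fold lower (1.02 to 6.42), with a median over 8 genes of 0.09 (percentile 68.9) that was -0.33 with zero counts at their bound. In ethylene response HLS1 was 3.58-fold lower (1.13 to 14.9) and ERF1 3.07-fold lower (1.60 to 6.27), and the median of 0.19 (percentile 84.6) and the mean of -0.22 differ in sign. ARR3 had 12 counts against 1, a ratio of 11.7 (1.73 to 501), the only one of 11 cytokinin genes (median 0.13, percentile 73.3). The haemoglobin gene HB1 was 2.70-fold lower (1.43 to 5.42), the only one of 6 low-oxygen genes (median 0.26, percentile 89.7). In the seed storage list OLEO2 (0 to 8 counts, at least 2.61-fold) was higher and SESA1 (25 to 6 counts) 4.26-fold lower (1.71 to 12.7), and the median of -0.65 (percentile 7.36) turned to 0.63 with zero counts at their bound. No brassinosteroid (0 of 8, median 0.35, percentile 98.2), cell division (0 of 20, median -0.26, percentile 1.54), shoot apex (0 of 2, median 0.41, percentile 85.2) or PIF, HD-ZIP II and PRE gene (0 of 12, median 0.09, percentile 72.5) met it.

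Beyond the lists, the largest increases in arf7 by the same rule were in the PR-1-LIKE gene (0 to 70 counts, at least 22.8-fold), AIR1, named for its induction by auxin in root cultures, at 66.2-fold (25.6 to 245), the extensin gene EXT6 (2 to 105 counts, 51.3-fold with an interval of 13.9 to 429), UNE11 (1 to 47 counts, a ratio of 45.9 with an interval of 7.85 to 1852) and UMAMIT25 (0 to 19 counts, at least 6.19-fold). The largest decreases were in TAT3, a jasmonate-responsive aminotransferase gene, at 29.1-fold (15.1 to 64.4), FAMT at 13.2-fold (8.80 to 20.7), ERD9 at 7.16-fold (4.57 to 11.8), MSRB7 at 6.86-fold (3.51 to 15) and the jasmonate synthesis gene AOC1 at 6.56-fold (5.46 to 7.94).

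Between the mock libraries, list medians on both sides lay beyond the range of random lists, with 10 of 25 SAUR genes and 6 of 18 photosynthesis genes lower in arf7 and 4 of 6 flavonoid genes higher. GH3.1 was 13.1-fold lower (4.82 to 49.7), GH3.5 8.44-fold lower (7.38 to 9.69) and GH3.6 2.35-fold lower (2.16 to 2.56) in arf7. EXPA8 was 18.4-fold lower (11.4 to 31.4) and PRE6 16.1-fold lower (7.55 to 40.9). LHCB1.1 (AT1G29920, chromosome 1, 10474784 to 10475959) was 53.0-fold lower (40.1 to 71.6), with reads possibly shared with its near-identical copies. The size rule was met by 404 loci as higher in arf7 and 398 as lower, 4.63% of those compared, against 198 and 146 in the authors' deposited table. This comparison shares the arf7 mock library with the NAA response in arf7 and the Col-0 mock library with that in Col-0. A value too high in arf7 mock alone would read as higher here and as lower with NAA in arf7. Those were the directions of CHS and CHI, so such pairs are not independent results.

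Of 25 SAUR genes 10 were lower in arf7 and 0 higher (median -1.75, percentile 0.00, or -0.54 without the near-identical copies). SAUR15 had 0 counts in arf7 against 17, at least 5.59-fold lower, and SAUR21, SAUR24 and SAUR65, from groups of near-identical copies, were at least 4.60-fold, 5.26-fold and 3.62-fold lower. Of 21 Aux/IAA genes 3 were lower (median -0.38, percentile 0.01, or -0.48 with zero counts at their bound), IAA1 at 4.30-fold (3.18 to 5.91), IAA5 at 3.07-fold (1.41 to 7.39) and IAA3 at 2.13-fold (1.92 to 2.36). The GH3 and DAO list had 3 of 8 lower (median -0.08, percentile 25.2). In the LBD list PUCHI, a regulator of lateral root primordia, was 9.21-fold lower (3.98 to 26.2), 1 of 4 (median -1.01, percentile 0.03). AFB1 was 2.24-fold lower (1.75 to 2.90), 1 of 6 receptor genes (median -0.19, percentile 6.51). Auxin biosynthesis had YUC2 2.42-fold higher (1.51 to 3.98) and YUC9 3.95-fold lower (1.44 to 13.5) among 7 genes (median -0.35, percentile 6.60). No ARF (0 of 12, median 0.22, percentile 97.9) or auxin transport gene (0 of 17, median -0.09, percentile 16.1) met the rule.

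GA20OX1 (AT4G25420, chromosome 4, 12990884 to 12992458), a gibberellin synthesis gene, had 54 counts in Col-0 and 0 in arf7, at least 17.8-fold lower, and GA20OX2 was 3.16-fold lower (1.51 to 7.20), while GA3OX2 was 2.82-fold higher (1.27 to 6.86). The gibberellin list as a whole had 2 of 11 lower and 1 higher (median -0.23, percentile 4.68). Of 12 PIF, HD-ZIP II and PRE genes 3 were lower (median -0.49, percentile 0.01), including PRE1 with 0 counts in arf7 against 16, at least 5.26-fold, and HAT3 at 2.43-fold (1.84 to 3.25). Among 13 expansins 3 were lower and 1 higher (median -0.03, percentile 39.0), EXPA11 being 11.3-fold lower (4.96 to 32.0) and EXPA16 2.57-fold higher (1.38 to 5.02). XTH17 was 2.88-fold lower (1.98 to 4.28), 1 of 12 XTH genes (median -0.24, percentile 1.14). In ethylene biosynthesis ACS7 was 5.97-fold higher (2.92 to 13.8) and ACS11 3.81-fold lower (2.71 to 5.46) among 8 genes (median -0.53, percentile 0.16, but -0.20 and within the range of random lists with zero counts at their bound).

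Flavonoid genes had 4 of 6 members higher in arf7 (median 1.29, percentile 100), with CHS at 4.63-fold (4.31 to 4.99) and CHI at 3.97-fold (2.97 to 5.38). The photosynthesis list had 6 of 18 lower and 4 higher (median -0.67, percentile 0.00), with LHCB2.1 at 22.9-fold lower (18.0 to 29.6), LHCB3 at 10.4-fold (9.58 to 11.3) and LHCA4 at 6.49-fold (6.19 to 6.81). In the defence and jasmonate list LOX2, a jasmonate synthesis gene, was 6.43-fold higher (4.13 to 10.47) and WRKY53 3.22-fold lower (2.77 to 3.75) among 10 genes (median 0.23, percentile 98.3). CKX6, a cytokinin oxidase gene, was 2.37-fold higher (1.95 to 2.88), 1 of 11 cytokinin genes (median 0.20, percentile 96.1, or 0.13 with zero counts at their bound). PCO1 was 2.20-fold higher (1.23 to 4.08), 1 of 6 low-oxygen genes (median 0.23, percentile 90.14), and PHT1;4 was 2.76-fold higher (1.67 to 4.73), 1 of 13 root markers (median -0.00, percentile 44.8). SESA1 was 3.62-fold higher (1.52 to 9.91), 1 of 4 seed genes (median 0.53, percentile 86.3, or 0.02 with zero counts at their bound). The lists with no member past the rule were ethylene response (median -0.23, percentile 4.62), brassinosteroid (-0.35, percentile 0.46), cell division (-0.09, percentile 16.4), shoot apex (0.07, percentile 61.6), abscisic acid (0.17, percentile 78.1) and heat shock (0.56, percentile 99.8).

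Among loci with a symbol and a mean of at least 10 CPM, the largest increases in arf7 were in PLA2A, a patatin-like phospholipase gene (3 to 62 counts, 20.9-fold with an interval of 6.84 to 104), the glucosyltransferase genes DOGT1 at 6.97-fold (4.82 to 10.4) and UGT85A1 at 4.85-fold (3.39 to 7.11), AIR3 at 5.31-fold (3.31 to 8.92) and CHS. The largest decreases were in LHCB1.1, LHCB2.2 at 40.3-fold (28.9 to 58.1), LHCB2.1, BBX28 at 21.1-fold (10.01 to 53.5) and UMAMIT25 (10 to 0 counts, at least 3.29-fold). Without the Col-0 NAA library in the scaling and the filter, 413 loci were higher and 381 lower in mock, and 605 were higher and 759 lower with NAA in arf7.

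**Figure D2:**
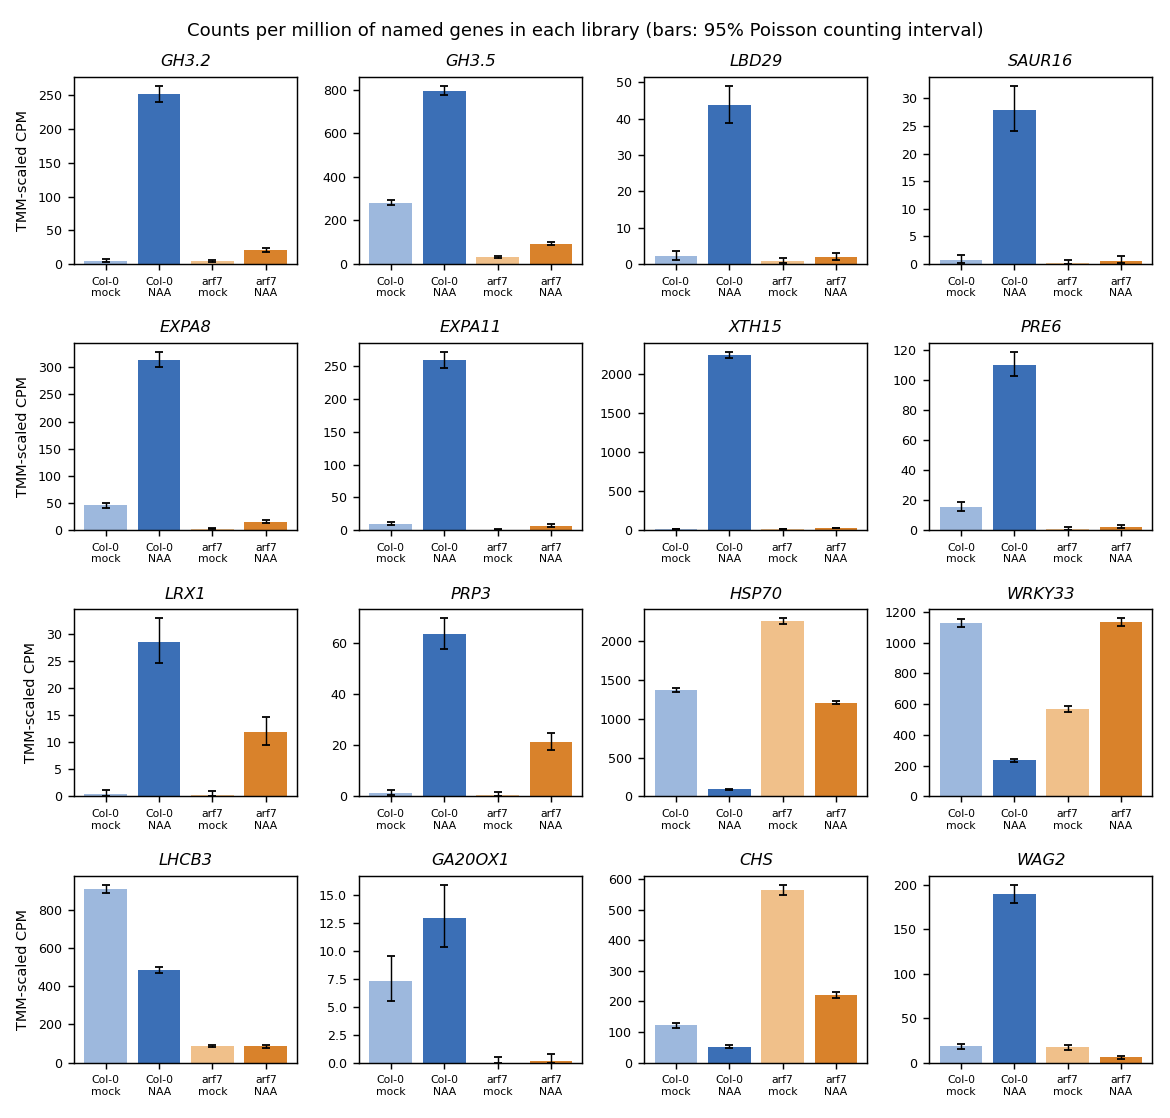
TMM-scaled CPM (counts scaled to a common library size; vertical axes from 0) of 16 named genes in the 4 libraries, 1 bar per library with its 95% Poisson counting interval. GH3.5 stands at 280.8 and 795 CPM in Col-0 mock and NAA and at 33.3 and 92.7 CPM in arf7, and LHCB3 at 912 and 485 CPM in Col-0 and at 87.8 and 84.8 CPM in arf7.

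With NAA present, 1869 loci were higher and 2446 lower in arf7 than in Col-0, 24.9% of those compared. Which direction held more loci depends on the scaling, since total counts gave 2263 higher and 2178 lower. XTH17 was 154-fold lower in arf7 (110 to 223), XTH15 85.6-fold lower (74.3 to 99.2), SAUR16 51.9-fold lower (19.9 to 192) and GH3.2 12.3-fold lower (10.4 to 14.6). HSP70 was 13.0-fold higher (12.0 to 14.1) and IGMT1, an indole glucosinolate methyltransferase gene, 42.0-fold higher (35.1 to 50.8). The authors' deposited table lists 1683 loci as higher and 1930 as lower, of which 1432 and 1836 met the size rule in the same direction. This comparison also rests on the Col-0 NAA library that stood apart from the other 3.

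Of 25 SAUR genes 21 were lower in arf7 (median -3.34, percentile 0.00, or -1.77 without the near-identical copies), of 8 GH3 and DAO genes 4 lower and 1 higher (median -1.02, percentile 0.14), and of 21 Aux/IAA genes 8 lower and 1 higher (median -0.66, percentile 0.08). SAUR22 had 0 counts in arf7 against 75, at least 27.3-fold lower. GH3.1 was 22.7-fold lower (14.2 to 38.7), IAA19, a repressor of hypocotyl growth responses, 5.06-fold lower (4.26 to 6.03) and IAA29 11.6-fold lower (4.66 to 37.1). All 4 measured genes of the LBD list were lower (median -2.62, percentile 0.13), LBD29 at 23.2-fold (13.6 to 42.9), LBD18 at 7.43-fold (4.68 to 12.4), PUCHI at 5.31-fold (3.02 to 9.97) and LBD16 at 2.75-fold (2.15 to 3.54). Auxin transport had 7 of 17 lower and 3 higher (median -0.86, percentile 0.03), with WAG1 33.5-fold lower (21.0 to 56.9), WAG2 32.0-fold lower (23.7 to 44.2) and PIN6 9.92-fold higher (4.32 to 28.0). Among the others, 3 of 12 ARF genes (median -0.38, percentile 4.97) and 2 of 6 receptor genes (median -0.73, percentile 1.1) were lower, with 1 ARF gene higher. Auxin biosynthesis had 3 of 7 lower and 1 higher (median -0.53, percentile 13.0), YUC8 at 20.2-fold lower (8.99 to 56.2).

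Among wall and growth genes, 8 of 13 expansins were lower and 3 higher (median -1.23, percentile 0.01), 5 of 12 XTH genes lower and 2 higher (median -0.85, percentile 0.09) and 11 of 12 PIF, HD-ZIP II and PRE genes lower (median -1.78, percentile 0.00). EXPA11 was 36.9-fold lower (28.0 to 49.6), EXPA8 19.9-fold (16.5 to 24.2) and PRE6 51.1-fold (31.3 to 89.9), and PRE1 had 0 counts against 83, at least 30.2-fold lower. In ethylene biosynthesis 6 of 8 were lower and 1 higher (median -1.49, percentile 0.05), ACS6 being the higher at 3.74-fold (3.47 to 4.04). In ethylene response 5 of 8 were lower (median -1.25, percentile 0.11), HLS1 at 54.3-fold (20.9 to 201). The gibberellin list had 5 of 11 lower and 1 higher (median -0.63, percentile 2.21), GA20OX1 with 1 count against 88, a ratio of 96.1 (16.8 to 3837), and GA3OX1 at 6.03-fold (4.21 to 8.86). Brassinosteroid genes had 2 of 8 lower (median -0.52, percentile 2.87), among them the synthesis gene BR6OX2 at 2.51-fold (2.17 to 2.90). Cytokinin genes had 5 of 11 higher and 2 lower (median 1.02, percentile 100), ARR7 at 14.6-fold higher (10.2 to 21.5).

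Heat shock genes were higher in arf7 with NAA, 6 of 7 (median 2.84, percentile 100), HSP90.1 at 18.6-fold (15.4 to 22.7). So were 6 of 10 defence and jasmonate genes, with 1 lower (median 1.72, percentile 100), CYP81F2 at 7.63-fold (5.8 to 10.2) and WRKY33 at 4.84-fold (4.59 to 5.11). All 6 low-oxygen genes were lower (median -2.03, percentile 0.04), PCO1 at 5.68-fold (4.22 to 7.78), and so were 3 of 4 abscisic acid genes (median -1.67, percentile 0.81) and 3 of 4 seed genes (median -2.52, percentile 0.66). Photosynthesis genes had 9 of 18 lower and 2 higher (median -0.97, percentile 0.00), and 11 of 13 root markers were lower (median -1.58, percentile 0.03), for example XTH14 at 5.33-fold (3.79 to 7.65). Flavonoid genes had 2 of 6 lower and 1 higher (median -0.54, percentile 13.0), CHS at 4.30-fold higher (3.83 to 4.84). Cell division had 1 of 20 higher and 1 lower (median -0.37, percentile 1.86), and neither shoot apex gene met the rule (median -0.19, percentile 39.7). Beyond the lists, the largest increases by the same rule included BGLU7 (1 to 238 counts, a ratio of 218 with an interval of 38.8 to 8647) and RPP4 at 57.7-fold (26.3 to 158). Among the largest decreases were UMAMIT36 (529 to 0 counts, at least 192-fold), the bHLH gene HEC2 (518 to 0 counts, at least 188-fold) and the transporter gene OCT1 at 185-fold (78.8 to 570).

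The difference in the NAA response itself was compared per locus. Of the 4891 loci that met the rule in Col-0, 3260 (66.7%) had a weaker response in arf7, 1765 of them higher and 1495 lower with NAA in Col-0. Of the 1426 loci that met the rule in arf7, 422 (29.6%) were called stronger, 146 higher and 276 lower, which means that the arf7 response lay further in its own direction and not that it was larger. The absolute log2 response was larger in arf7 for 304 of the 422 and smaller for 118, and 348 had the other sign in Col-0. The 156 loci that met the rule in opposite directions are in both counts, weaker and stronger. Among loci with a symbol and a mean of at least 10 CPM, the largest weaker responses were in UMAMIT36, with an arf7 minus Col-0 log2 difference of -10.19 (-17.12 to -3.27), PORA at -9.69 (-16.62 to -2.76), GH9B15 at -9.60 (-14.02 to -5.18), GRF7 at -9.58 (-14.21 to -4.94) and HEC2 at -9.43 (-14.38 to -4.47), each of them with 4 counts or fewer in every library but Col-0 NAA. The largest differences called stronger were in PLA2A at -7.92 (-9.56 to -6.28), SULTR3;1, a sulfate transporter gene, at -6.78 (-8.22 to -5.33), PDC3 at -6.30 (-7.82 to -4.78), PME61, a pectin methylesterase gene, at -5.27 (-6.05 to -4.49) and WAG2 at -4.89 (-5.45 to -4.33). These 5 were lower with NAA in arf7 and higher with NAA in Col-0.

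By list, SAUR genes had 6 of 25 weaker and 2 stronger (median difference -1.21, percentile 0.03), expansins 8 of 13 weaker (median -1.03, percentile 0.07), XTH genes 7 of 12 weaker and 1 stronger (median -1.04, percentile 0.02) and low-oxygen genes 5 of 6 weaker and 1 stronger (median -2.39, percentile 0.02). GH3 and DAO genes had 3 of 8 weaker (median -0.37, percentile 7.60), and root markers 4 of 13 (median -1.49, percentile 0.15). Over the loci chosen on Col-0 the slope of the arf7 response on the Col-0 response was 0.181 and 66.5% had the same sign. Over the loci chosen on arf7 the slope of the Col-0 response on the arf7 response was 0.876 and 74.9% had the same sign. Choosing loci by their response in a library favours large values there, so each slope holds for its own choice. Both responses shared 402 higher loci, against 102.7 for independent lists, and 311 lower loci, against 98.0. The responses share no library, and their Pearson correlation across the 17317 loci was 0.375 and the Spearman correlation 0.274, where genes are not independent replicates.

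**Figure D3:**
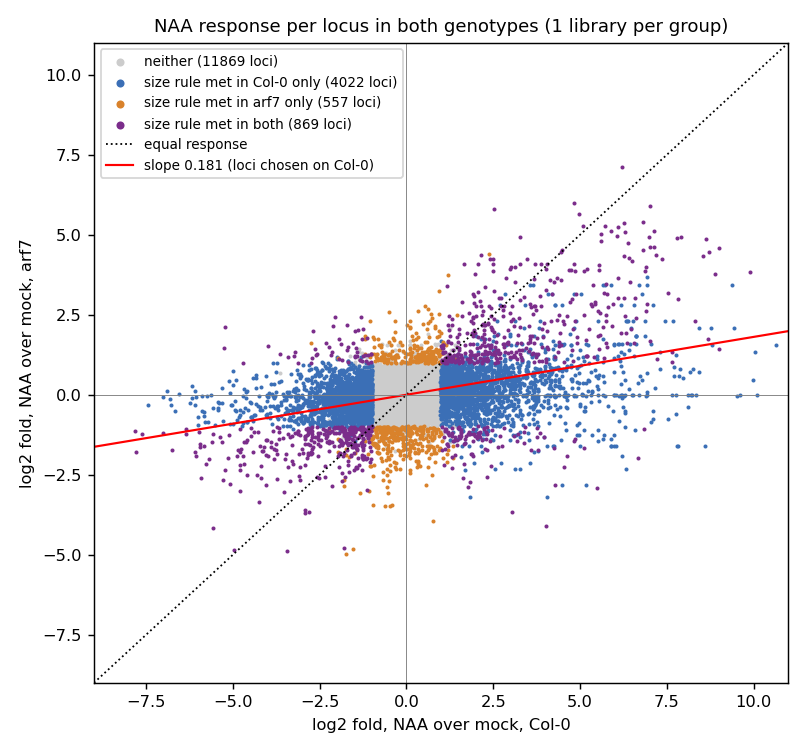
Log2 fold of NAA over mock per locus in Col-0 (horizontal axis) and in arf7 (vertical axis), coloured by where the size rule was met, with the line of equal response dotted and the slope of 0.181 in red. Most loci that met the rule in Col-0 lie nearer to 0 in arf7, and 402 were higher and 311 lower in both genotypes.

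The additive model of genotype and NAA treats the interaction as error. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 loci passed an adjusted p of 0.05 for NAA and 0 for genotype, while 1400 and 578 had an unadjusted p under 0.05. The smallest adjusted p by edgeR was 0.340 for NAA and 0.233 for genotype. DESeq2 called 249 loci for NAA, 169 higher and 80 lower, and 69 for genotype, 6 higher and 63 lower in arf7, and limma-voom called 0 for both. The common biological coefficient of variation of the edgeR fit was 0.360, which includes the difference in response between the genotypes. At that value edgeR recovered 1% of loci simulated with a 2-fold change and 17% of those with a 4-fold change, so the 0 calls exclude little.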

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

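The touch and root tissue tests were written before their own values were computed but were prompted by counts already seen, and the tests chosen only after the result was seen were those of light exposure and both of the LHCB genes. The results listed first were flagged because the NAA response went opposite ways in the genotypes. None of these differences was tested, since each group has 1 library.

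With NAA, 104 loci were higher in Col-0 and lower in arf7, and 52 were lower in Col-0 and higher in arf7. Loci that went the same way were more, 402 higher and 311 lower, against 102.7 and 98.0 for independent lists. No such number was computed for the opposite responses, so the 104 and 52 are not shown to be an excess. Among the 104, members of the gene lists have an arf7 minus Col-0 difference in log2 response of -3.40 (GA3OX1), -2.79 (HB1), -4.89 (WAG2), -5.52 (HLS1) and -3.05 (KIN1). ACS6 has a difference of 2.90 in the other direction. The abscisic acid list has a median difference of -1.94. The rapid touch and wound list, written later, has a median difference of 2.24.

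The Col-0 NAA library stands apart from the other 3, with a Spearman correlation across loci of 0.847 to 0.881 with them against 0.968 to 0.981 among them. The test of RNA degradation or fragmentation found no sign particular to this library. Its closest pair differed by 0.160 points in covered percent and by a correlation of 0.0273 with transcript length, while the other pairs reached 0.560 points and a size of 0.0964. Both of these largest values belong to pairs with Col-0 mock, so the test could miss a smaller shift in the Col-0 NAA library. RNA composition was outside the test, and mitochondrial loci took 0.704% of the counts of this library against 0.0808% to 0.102% in the others. Handling before extraction may contribute, since 17 rapid touch and wound genes had a median of -0.94 (percentile 0.03), and the list was lower than in Col-0 mock (-1.93, 11 of 17 lower) and than in arf7 NAA (11 of 17 higher there, median 1.295). In arf7 the list was higher with NAA (0.66, 6 higher, percentile 100). The 2 mock libraries also differed by -0.94 in this list and still correlated at 0.981. The heat shock list, fixed as a sign of handling stress, was lower in this library too (median -2.82 over the other 3, percentile 0.00) and differed by 0.56 between the mock libraries. Different light at harvest cannot be told apart from the NAA treatment in this library. Light-induced regulators (median log2 0.58 over the other 3) and the photosynthesis and greening list (1.17, percentile 100) go with more light, as do its members ELIP1 and ELIP2 at 140-fold and 245-fold over Col-0 mock. The greening list also holds PORA, a gene of dark-grown seedlings, with 373 counts here and 0 in Col-0 mock. It holds LHCB genes too, which were lower in arf7 mock than in Col-0 mock, so its 1.17 partly reflects the arf7 libraries in the reference. Genes high in darkness (1.64) go the other way, and the photosynthesis list was lower than in Col-0 mock (-0.56). An NAA response that depends on ARF7 remains open and untested, as genotype and treatment meet in this library without a replicate.

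Root and root hair markers were higher with NAA in both genotypes (medians 3.87 in Col-0 and 3.52 in arf7, the latter 1.38 with zero counts at their bound). More root tissue in the NAA samples is a candidate explanation that its test left standing, since root genes outside hairs had medians of 4.35 in Col-0 (percentile 100) and 0.51 in arf7 (percentile 99.9). The test cannot tell root tissue from root genes induced within the hypocotyl, since either would raise root genes outside hairs. Among these genes in arf7, TIP2;3, TIP4;1 and BRN1 stood well above the median (log2 2.61, 2.85 and 4.94), while CASP1 of the endodermis stood at 0.27. Of the 12 root genes 10 had at least 1 CPM in each mock library, against 4 and 3 of the 13 root and root hair markers, so the hypocotyl samples held most of these transcripts without NAA. Induction of root hair genes by auxin inside the hypocotyl remains open and untested.

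The 7 LHCB genes measured in the photosynthesis list or among the LHCB1 copies were all lower in arf7 mock (median log2 -2.60, SD 1.56). LHCB2.2, which is in neither, was lower too. Less cotyledon or greening tissue would lower other photosynthesis genes as well, but 8 others had a median of -0.056 (SD 1.44), with 1 lower and 2 higher. Those 8 were chosen after the result was seen and include RBCS genes, whose reads are uncertain. The whole fixed photosynthesis list, LHCB genes included, had a low median in arf7 mock with members lower and higher. The test therefore shows only that these 8 genes did not fall as a set. Reads moved between near-identical LHCB1 copies are argued against as the whole cause. LHCB3 was 10.4-fold lower (9.58 to 11.3), and the 5 LHCB1 copies summed to 85503 counts in Col-0 and 27121 in arf7, 3.11-fold lower (3.07 to 3.15). Moved reads could still account for part of the larger fold of LHCB1.1 alone. A difference of genotype remains open as a hypothesis, found and examined in the same 2 mock libraries. With NAA the 5 LHCB1 copies summed to 69596 counts in Col-0 and 32263 in arf7, a smaller difference than in mock.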

How the results depend on the processing

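The alternatives chosen after seeing the data were the transcript models as deposited, loci with 1 listed model, and scaling without the Col-0 NAA library. No paired analysis was possible because each group has 1 library and no replicate number to pair by, although the additive model does set NAA against mock within each genotype. No replicate could be left out. Depth limits loci near 1 CPM, where a count of 0 allows about 0.4 CPM. Scaling by total counts or DESeq2 size factors, no filter, the transcript models, loci with 1 listed model and scaling without the Col-0 NAA library left each count of loci they were run for within 1.5 times (4 of the counts for the last), and the slope moved little under any setting. With total counts the median log2 of all loci for arf7 over Col-0 with NAA was 0.128, against 0.00790 with TMM, and the share of higher loci among those past the rule went from 43.3% to 51.0% there and from 53.7% to 49.7% with NAA in Col-0. RPKM with 0.1 added gave 51.9% and 48.9%.

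Fewer loci pass stricter rules by construction. A fold of at least 3 gave 1739 higher and 1156 lower with NAA in Col-0, 293 and 283 in arf7, 157 and 157 between genotypes in mock, 924 and 1522 with NAA, 1903 weaker and 145 stronger. A mean of at least 5 CPM gave 1596 higher in Col-0, 367 and 440 in arf7, 192 and 204 in mock, 1500 lower between genotypes with NAA and 237 stronger. The deposited RPKM with 1 added gave 401 and 489 in arf7, 242 and 206 in mock and 260 stronger, since the added value shrinks low folds. With 0.1 added, 652 were higher in mock. The RPKM settings asked for the fold alone, without a counting interval, so loci with few reads could pass. Their share of the 652 was not counted. The authors' deposited tables give 333 and 484 in arf7 and 198 and 146 in mock. They hold only models with an FDR of at most 0.001, and the cause of the smaller counts was not tested.

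In the additive model edgeR called 0 for both effects under TMM, DESeq2 size factors, no filter and 1-model loci, and limma-voom called 0, whereas DESeq2 called 249 for NAA and 69 for genotype, with 1008 and 1679 adjusted p-values not given by the tool. The cause was not tested. Of 104 list medians, 66 lay beyond the range of random lists, and all 104 moved by no more than the SD of random lists under both scalings. Total counts turned the sign of 2 medians near 0, gibberellin with NAA in Col-0 (-0.03) and expansins in mock (0.04). Without a filter 21 moved by more, and the sign turned for flavonoid genes with NAA in Col-0 (-0.51), auxin biosynthesis in mock (0.01) and the shoot apex list between genotypes with NAA (0.25). Without near-identical members the SAUR median moved to 1.297 with NAA in Col-0, -0.54 in mock and -1.77 between genotypes with NAA, and was 0.74 with NAA in arf7. Taking means, 68 were the same, 34 moved and 2 reversed, the photosynthesis list with NAA in Col-0 (mean 1.02) and the abscisic acid list with NAA in arf7 (mean 0.18), as a few members with large values set the mean. The mean also turned the sign of auxin transport (0.01), ethylene response (-0.22) and seed storage (0.11) with NAA in arf7, whose medians lay within the range of random lists. Of 303 values of named genes, 2 no longer met the rule by total counts, CYCB2;1 with NAA in Col-0 (log2 0.93) and NCED3 in arf7 over Col-0 with NAA (-0.88).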

Other observations

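The loci in this paragraph fall outside the rule for named genes and were chosen after their values were seen. The most counted transcript model was that of AT3G09260 in Col-0 mock and that of AT3G26520 in Col-0 NAA. These loci went opposite ways with NAA in Col-0. PYK10 (AT3G09260), an ER-body beta-glucosidase gene, held 293803 counts in Col-0 mock, 52476 in Col-0 NAA, 232283 in arf7 mock and 180191 in arf7 NAA, 5.18-fold lower with NAA in Col-0 (5.13 to 5.23) and 1.32-fold lower in arf7 (1.31 to 1.33). AT3G26520, a tonoplast water channel gene that the files call TIP2, was 6.90-fold higher with NAA in Col-0 (6.79 to 7.01) and 3.0-fold higher in arf7 (2.94 to 3.07). AT4G29200, described as beta-galactosidase related, had 790 and 954 counts in the Col-0 libraries and 2 in each arf7 library. It and GA20OX1, at 54 and 88 counts in Col-0 and 0 and 1 in arf7, separate the genotypes with or without NAA.

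Organelle transcripts differed in the Col-0 NAA library. Mitochondrial loci took 0.704% of its counts against 0.0808% to 0.102% in the others, and 72.5% of those reads lay on RRN26, the large mitochondrial ribosomal RNA, which was 16.9-fold higher with NAA in Col-0 (16.2 to 17.62). The 27 mitochondrial loci compared had a median log2 of -0.86 there, with 4 higher and 11 lower, and of -0.12 in arf7, with 0 higher and 0 lower. Of 65 chloroplast loci 36 were higher with NAA in Col-0 and 0 lower (median 1.07).

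With thresholds of 60 counts or more against 2 or fewer, chosen after seeing the data, 25 loci were on in Col-0 NAA alone and 5 were off in it alone, and each other library had 0 of either kind. The 25 include UMAMIT36, UMAMIT34, PORA, HEC2, ACS5, IAA20, the oleosin gene OLEO3 (261 counts) and the peroxidase-family gene AT1G49570 (408 counts). The 5 include BGLU7, EP1 and AT4G22505, which had 494, 0, 610 and 466 counts in Col-0 mock, Col-0 NAA, arf7 mock and arf7 NAA.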
